A study of Caenorhabditis elegans with 2 samples.

How the data were processed

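Peaks of PHP-3 tagged with EGFP were measured by ChIP-seq in whole L4 larvae of 1 strain, in 2 biological replicates, per the labels; both formed a single group. The authors deposited peak lists on assembly ce11, per the file listing that came with the samples. The aligner, the peak caller and their versions are not given in the sources used here. The labels name a possible control experiment, whose data are not analysed here, and the signal tracks in the listing are not used here.

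In all, 8 lists were used: a ranked and a thresholded list per replicate, and 2 ranked and 2 thresholded lists of the whole series. The authors gave each peak a score scaled from its irreproducible discovery rate (IDR), a rate of disagreement between paired lists, and the lowest score in each deposited thresholded list was 830. The signal value is the peak height as the authors' deposited lists give it, and it was used to rank and describe peaks within a list. The −log10 q value is also the authors', and it was used only as another ranking. A series-wide ranked list pairs the replicates: its 2 sets of input intervals matched rows of the replicates' own ranked lists for 46152 and 55508 of 95772 peaks. The other series-wide ranked list held 96056 peaks, and only 2 had an input interval in a replicate's own ranked list. The lists that it pairs are therefore unknown here. Main results rest on the larger series-wide thresholded list (3559 peaks), which was kept from that other ranked list. The conservative list, kept from the one that pairs the replicates, held 3495, of which 2974 had a summit of the larger list. Most peaks (89.1%) had 1 width, 324 bp, so interval lengths carry little information. Read numbers are unknown, so no precision that depends on depth is given, and intervals on shares cover the counting of peaks or genes only.

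Genes and sequence came from Ensembl release 115 and the RefSeq genome of assembly WBcel235, which has ce11 coordinates; no peak ended beyond its chromosome. A summit is the position the lists name within each peak. Promoters reached from 1 kb upstream to 200 bp downstream of the outermost annotated 5′ end, and took priority over coding exons and UTRs, then introns, then intergenic sequence. Replicate signals at a series-wide peak are the highest signal of any overlapping peak in that replicate's ranked list. Overlap required 1 bp. Chance overlap and location came from 1000 circular shifts, the signal difference from 100000 permutations, and lists, motifs and chromosome segments from Fisher's exact test, all two-sided but the overlap. Log2 odds ratios of gene lists had 0.5 added to each cell, and those of chromosome segments had nothing added. P-values were adjusted by Benjamini-Hochberg over 22 lists, 10 motifs or 6 chromosomes. Motif windows reached 50 bp to each side of a summit; control windows of equal length were centred 400 bp to each side, and left out where they met a summit window. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

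The gene lists, motifs, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 20 strongest peaks found in both replicates' lists, every Hox gene and cofactor, up to 4 marked members per list with the highest signal, and the php-3 locus; asp-1, pho-1, elt-7, hsp-6, hsp-16.2, hsp-16.41 and atfs-1 fell outside it and were named after their values were seen. The alternatives fixed with them were the conservative list, the stronger-signal part of the list (peaks above its median), each replicate's own list, upstream windows of 500 bp and 2 kb, the nearest 5′ end, a background of genes with class names, chromosome length, windows of 51 and 201 bp, dinucleotide shuffles (10 per window), overlap of 50% of both intervals, summits within 100 bp, and other rankings. Leaving out summits within 1 kb of a tRNA gene, leaving out peaks of signal under 50, and 50% overlap for the count of shared peaks were chosen after seeing the data. The statistics were tested on simulated data of 3559 summits. With 30% of summits moved into promoters the location test returned a ratio of 2.16; with the strict posterior Hox motif planted in 20% of windows the motif test returned a ratio of 5.69. Over 20 sets of random summits, 0 calls were made for promoter location, 0 for motifs and 1 for gene lists. Those summits were placed independently of each other and of genes, with fewer shifts for location and without the tRNA and microRNA lists. The counts therefore do not show how often clustered peaks, or those 2 lists, would be called wrongly. An earlier single random set, replaced when the number of sets was raised to 20, had given a motif call.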

Results

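Binding of PHP-3, a posterior-group Hox protein of the nematode Caenorhabditis elegans, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole L4 larvae, 48 hours of age. The worms carried an EGFP tag at the php-3 gene, and chromatin was recovered with an antibody against GFP. The data comprised 2 biological replicates of 1 strain and stage, so no comparison between conditions was made. Peak lists were analysed, and read depth is unknown. The list made from both replicates held 3559 peaks covering 1069 kb, or 1.07% of the genome (ce11). The replicates' own lists held 1728 peaks in replicate 1 and 2000 peaks in replicate 2.

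The first question was how far the replicates shared their peaks. Of replicate 1's peaks, 1269 (73.4%, exact binomial 95% interval 71.3 to 75.5) overlapped a replicate 2 peak by at least 1 bp. In the other direction, 1281 of 2000 replicate 2 peaks (64.05%, interval 61.9 to 66.2) overlapped one of replicate 1. Moving positions along each chromosome by 1000 random circular shifts gave a mean of 19.02 shared replicate 1 peaks and at most 44 (one-sided permutation p = 0.000999, the smallest the shifts can give). Among the series-wide peaks, 1257 lay in both replicates' own lists, 385 in replicate 1's alone, 636 in replicate 2's alone and 1281 in neither. In the quartile of highest signal, 842 of 890 peaks (94.6%) were in both own lists, against 40 of 890 (4.49%) in the lowest quartile (Fisher's exact test, two-sided, −log10 p = 384). The series-wide signal and the own lists come from the same 2 replicates. Part of this relation is therefore built in, and the p-value measures no independent support. Of the 40 in the lowest quartile, 36 had signal values under 50. The quartiles between held 2.25% and 39.9% in both. With overlap of 50% of both intervals the shares were 70.9% in the highest quartile and 0.225% in the lowest. Across 3486 paired peaks, which are not independent replicates, the replicates' signal values had Spearman's rho 0.63 and Pearson's r 0.61 on the log2 scale. These peaks had already passed a limit on agreement between paired lists, though those lists did not match the replicates' own. Of the 95772 peaks of the ranked list that pairs the replicates, 31660 had both input intervals in the replicates' own ranked lists. Over those, Spearman's rho was 0.42, and the rest could not be compared. Ranked by −log10 q in place of signal, rho over the paired peaks was 0.25.

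**Figure D1:**
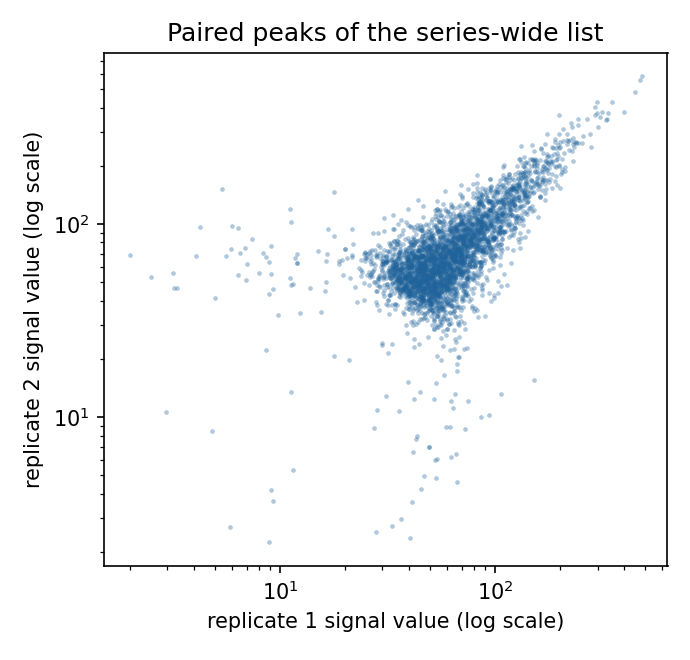
Signal values of replicate 1 (x axis) and replicate 2 (y axis), both on log scales in the authors' units, for 3486 paired peaks of the series-wide list; each point is a peak. The points widen toward low signal, and Spearman's rho over all of them is 0.63.

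The strongest peaks of the thresholded list stood near or in tlp-1, psa-3, T24E12.13 and nob-1. Ranked peaks of 3411 and 905.5 on X passed the same score but are not in that list, so the order holds within it only. The highest signal value of the list, 1143, belonged to a peak on chromosome IV (13707735 to 13708358), in intergenic sequence 4036 bp upstream of tlp-1 (WBGene00006580), a zinc-finger gene required for the shape of the tail tip. The next, at 1053, lay in an intron of psa-3 (WBGene00009560; X, 15408610 to 15409000), 887 bp downstream of its annotated 5′ end; psa-3 encodes a Meis-family homeodomain protein that acts in the tail's T cell lineage. The fourth, at 803, lay 587 bp upstream of nob-1 (WBGene00003779; III, 12084737 to 12085075), the Hox gene beside php-3. No excess of posterior genes passed the threshold. By promoter window, 2 of 14 tail and rectal epithelium genes were marked (exact adjusted p = 0.614). That list includes tlp-1, whose summit lay outside the window. By nearest 5′ end, 5 of 14 had a peak (35.7% against 13.3% of other genes, exact adjusted p = 0.118). Replicate 1 and replicate 2 gave signal values of 482 and 580 at tlp-1, 475 and 556 at psa-3, and 350 and 425 at nob-1. Sequences matching the posterior Hox motif TTTAYKR stood within 50 bp of these 3 summits: TTTACGA at tlp-1 (IV, 13708135 to 13708141), TTTATTA, CCGTAAA and CCATAAA at psa-3, and TAATAAA at nob-1 (III, 12084916 to 12084922), the last 3 read on the plus strand as reverse-strand matches. Only CCATAAA at psa-3 matched the strict form TTTATGR. Other motifs stood there too: GATA matches at tlp-1 (AGATAG) and psa-3 (TTATCA), and TATA-like matches at nob-1. Over all summits TTTAYKR was in 24.7% of windows, against 19.4% of windows beside them, so matches at single sites say little.

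The tagged gene and its neighbour carried a cluster of peaks. Of the 9 peaks whose nearest protein-coding 5′ end was that of php-3 or nob-1, 7 were nearest nob-1, with signal values of 92.8 to 803, and 2 of them lay within its gene body. The other 2 were nearest php-3 (WBGene00004024; III, 12074218 to 12077556), at 99.0 and 84.0, and neither lay in its promoter window; the stronger was in an intron of nob-1. Elsewhere among Hox genes and cofactors, ceh-60, which encodes a PBC-class homeodomain protein, had a summit 672 bp upstream of its 5′ end at 133, although neither replicate's own list held it. The cofactor gene ceh-20 had 2 overlapping peaks, at 110 and 8.82, with summits 1942 and 1733 bp upstream. Both had the same replicate signals, but overlapping peaks can take these from the same replicate peak. Whether the weaker is a second summit of the stronger therefore stays open. The nearest summits lay 14891 bp from ceh-13, 15592 bp from lin-39, 24718 bp from mab-5, 40298 bp from egl-5, 12072 bp from unc-62 (inside its gene body, at 143), 32336 bp from ceh-40, 52380 bp from pal-1 and 69325 bp from vab-7. As a list, 2 of 13 Hox genes and cofactors had a promoter summit (exact adjusted p = 0.609). By nearest 5′ end, 5 of 13 had a peak, psa-3 among them (38.5% against 13.3% of other genes, exact adjusted p = 0.106).

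**Figure D2:**
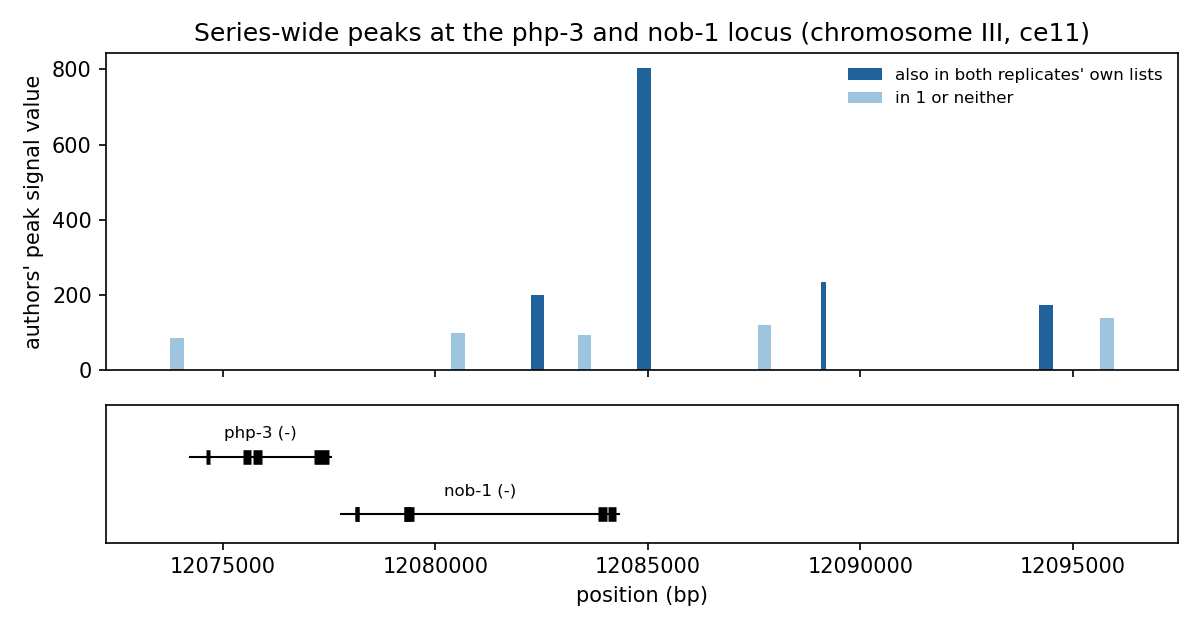
Series-wide peaks at php-3 and nob-1 on chromosome III (x axis, position in bp, ce11), with the authors' signal value of each peak as bar height; narrow peaks are drawn at least 120 bp wide. The lower panel shows the protein-coding genes with their coding exons as boxes, both on the minus strand, and the highest bar, at 803, stands 587 bp upstream of nob-1.

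The rest of the 20 strongest peaks found in both replicates' lists were near genes of several kinds. They included eel-1, a ubiquitin ligase gene (signal 721, 366 bp upstream), the ribosomal protein gene rpl-3 (661, 284 bp upstream), the ammonium transporter gene amt-4 (583, 172 bp upstream) and an intron of crh-2, a CREB-family gene (707). A peak at 714 lay between F44E5.4 and F44E5.5, and a peak at 580 between tbb-1, which encodes a beta-tubulin, and rib-2; as their promoters are divergent, either gene could be assigned. Others were T24E12.13 (935), F16G10.6 (751), K08F11.1 (725 and 660), T20B3.1 (688), K06G5.1 (666), rpa-2 (660), Y54G2A.49 (633), K08H2.10 (626), Y43F8B.2 (588) and K07D4.2 (568), each named by its nearest protein-coding 5′ end.

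Summits were concentrated in promoters, here 1 kb upstream to 200 bp downstream of the outermost annotated 5′ end. Promoters held 1405 of 3559 summits (39.5%), against a mean of 21.2% in shifted sets, a ratio of 1.86. Summits in 5′ UTRs were also above the shifted sets (1.12% against 0.568%), whereas coding exons held 6.86% against 19.9% and introns 24.1% against 30.4%. Each of these 4 had the smallest p that 1000 shifts can give (two-sided, 0.00200). The shares in 3′ UTRs (1.94% against 2.43%, permutation p = 0.0539) and in intergenic sequence (26.5% against 25.4%, p = 0.254) did not pass the threshold. Some of these results changed with the list. The excess in 5′ UTRs was not called without replicate 1 (ratio 1.502, permutation p = 0.170) or in the stronger-signal part of the list (permutation p = 0.0839). The share in 3′ UTRs was below the shifted sets in all 8 alternatives and passed the threshold in 5, of which 2 were chosen after seeing the data; the 5 included the conservative list (ratio 0.730, permutation p = 0.0260) and replicate 1's own list, that is without replicate 2 (0.594, p = 0.00799). Intergenic sequence passed it, above the shifted sets, in 4 of 8, among them the lists without replicate 1 (1.097, permutation p = 0.0320) and without replicate 2 (1.12, p = 0.0180). For coding exons the ratio was 0.344 in the main list, 0.217 without replicate 1 and 0.146 without replicate 2. Promoter peaks had a median signal value of 127 against 117 for other peaks, a difference of 10.05 (permutation test, two-sided, p = 1e-05, the smallest its 100000 resamples can give). The difference was 5.97 without replicate 1 and 4.65 without replicate 2. Many worm transcripts are trans-spliced, so the annotated 5′ end of a gene may lie downstream of where transcription starts.

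The X chromosome carried more summits than its genes would give. It held 839 summits (23.6%) but 13.7% of protein-coding genes, a ratio of 1.72 (exact binomial test, two-sided, adjusted p = 7.72e-56), and against its share of chromosome length the ratio was 1.33. Chromosome III was also above its gene share (ratio 1.11, exact adjusted p = 0.0179), while V (0.742, exact adjusted p = 1.34e-19), IV (0.848, exact adjusted p = 9.25e-05) and I (0.901, exact adjusted p = 0.0179) were below it. Chromosome II did not differ by this test (0.945, exact adjusted p = 0.143). The call on V was kept in all 7 alternatives. That on III was kept in 3 of 7: it ended without replicate 1 (ratio 1.08, exact adjusted p = 0.156), without replicate 2 (1.03, 0.594), in the stronger-signal part of the list (0.9994) and against chromosome length (1.06, 0.125). That on IV ended without replicate 1 (0.898, exact adjusted p = 0.0648) and without replicate 2 (0.927, 0.275), and that on I without summits near tRNA genes (0.919, 0.0679), an alternative chosen after seeing the data. Over the 6 chromosomes the chi-square statistic was 340 (p = 2.17e-71). On the autosomes, 40.1% of 2720 summits lay in the central segment, as long as each arm, against 38.1% of gene 5′ ends (log2 odds ratio 0.12 ± 0.06 (SE), Fisher's exact test, two-sided, p = 0.0439). The log2 odds ratio was 0.37 without replicate 1, 0.32 without replicate 2 and 0.34 in the stronger-signal part of the list. Neighbouring peaks are not independent, so these p-values are too small.

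By promoter window, tRNA and ribosomal protein genes had the highest shares of the 22 lists in the main peak list. Of 612 tRNA genes, 279 (45.6%) had a summit in the promoter window, against 7.95% of protein-coding genes (log2 odds ratio 3.28 ± 0.12 (SE), exact adjusted p = 4.34e-129). Of 76 ribosomal protein genes, 28 (36.8%) did (2.79 ± 0.34, exact adjusted p = 1.63e-11). By nearest 5′ end their share was 31.6%, below those of heterochronic genes (58.3%) and intestinal genes (57.1%). None of the 20 rRNA genes, which were in no list, had a summit in the window. Without replicate 1, 174 tRNA genes were marked, and without replicate 2, 155 tRNA genes and 17 ribosomal protein genes. In the conservative list the share of ribosomal protein genes was 39.5%, below that of stress and insulin signalling genes (42.1%). Without replicate 1 it was 25%, as was that of heterochronic genes. The strongest summits at ribosomal protein genes were those of rpl-3 (661), rpl-35 (482), rpl-20 (455) and rpl-15 (417), although Y17G9B.5 shares the summit of rpl-20 and K11H12.8 that of rpl-15. The strongest summit in a tRNA window (542, on V) lay 909 bp upstream of WBGene00023221, in an intron of pxn-1 and within 300 bp of a snoRNA gene, so it need not belong to the tRNA gene. The next were at the neighbours WBGene00023110 and WBGene00023111 on X (349, 1 shared summit) and at WBGene00014333 on X (322). Histone genes were also above the background, with 14 of 72 (19.4%; log2 odds ratio 1.53 ± 0.42, exact adjusted p = 0.00779), among them his-37 (296), the divergent his-5 and his-6 (166, 1 shared summit) and his-24 (145). With replicate 1's own list alone, that is without replicate 2, the histone log2 odds ratio was −0.31 (exact adjusted p = 1; over the 10 alternatives adjusted p was 0.000457 to 1). Tests were Fisher's exact, two-sided, adjusted by Benjamini-Hochberg over 22 lists; clustered and divergent genes share summits, so their p-values are too small.

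Intestinal genes formed another marked group, with 7 of 21 members (log2 odds ratio 2.59 ± 0.65 (SE), exact adjusted p = 0.00622). They were elt-2 (signal 236), which encodes the GATA factor of the intestine, the peptide transporter gene pept-1 (165), spl-1 (147), the vitellogenin gene vit-2 (121), asp-1 (113), pho-1 (94.0) and elt-7 (83.7). Heterochronic genes, which time larval development, had 4 of 12 members (2.62 ± 0.84, exact adjusted p = 0.0429): ain-1 (186), lin-28 (146), lin-66 (137) and alg-1 (103). Stress and insulin signalling genes had 5 of 19 (2.14 ± 0.72, exact adjusted p = 0.0448), the chaperone genes hsp-60 (414, a summit shared with Y22D7AL.10), hsp-1 (128), hsp-4 (121) and hsp-6 (98.3) and the unfolded protein response gene xbp-1 (212); these members are mostly chaperones, and no insulin pathway gene was among them. In the conservative list 8 of 19 were marked (log2 odds ratio 3.13 ± 0.65), the other 3 being hsp-16.2 and hsp-16.41 (both 89.6, so possibly 1 shared summit) and atfs-1 (70.1). Without replicate 1 or without replicate 2, 3 of 19 were marked. Without replicate 2, heterochronic genes had 2 of 12 members and intestinal genes 2 of 21. The heterochronic call passed the threshold in 4 of 10 alternatives (adjusted p 0.00211 to 0.431), the stress call in 3 of 10 (0.000348 to 0.682) and the intestinal call in 8 of 10 (5.55e-05 to 0.579), the last not in the stronger-signal part of the list nor without replicate 2 (log2 odds ratio 1.54).

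Cuticle collagen genes were marked less often than other genes. Of 176 collagen genes, 4 (2.27%) had a promoter summit (log2 odds ratio −1.74 ± 0.69 (SE), exact adjusted p = 0.0126): col-38 (139, a summit shared with rpl-5), col-63 (137), col-71 (99.6, shared with Y49F6B.2) and col-85 (11.6, within 300 bp of a tRNA gene). With peaks of signal under 50 left out, 3 of 176 were marked. Without replicate 1 and without replicate 2, 0 of 176 were marked, so the size of the log2 odds ratios (−4.13 ± 2.04 and −3.97 ± 2.04) depends on the 0.5 added to each cell. The call ended with a 500 bp upstream window (exact adjusted p = 0.0643), in the stronger-signal part of the list (0.0845) and with assignment to the nearest 5′ end (0.862), within a range of 0.00243 to 0.862 over 10 alternatives.

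The lists of other tissues and pathways did not pass the threshold. Wnt signalling had 2 of 22 members, mig-1 (190) and bar-1 (174), exact adjusted p = 0.930. Tail and rectal epithelium had 2 of 14, nob-1 and the DM-domain gene mab-3 (156), exact adjusted p = 0.614. By nearest 5′ end it had 5 of 14, and the exact adjusted p was 0.118. Germline genes had 3 of 22 (exact adjusted p = 0.609), cgh-1 (144), nos-3 (89, shared with Y53C12B.1) and fbf-2 (87.9, shared with nspg-3). Single members were marked among moulting genes (1 of 19, myrf-1, 135), pharynx genes (1 of 12, pha-4, 151), neuron identity transcription factors (1 of 26, unc-3, 82.9) and pan-neuronal genes (1 of 18, unc-11, 98.5), with exact adjusted p of 1, 1, 0.930 and 1. No summit was in the promoter window of the 16 hypodermal and seam cell transcription factors (exact adjusted p = 0.928), the 20 body wall muscle genes (0.733) or the 16 vulva and uterus genes (0.928). Among nuclear hormone receptors, 24 of 269 were marked (exact adjusted p = 0.928), led by nhr-68 (381, shared with H12C20.7), nhr-99 (304), nhr-35 (203) and nhr-256 (202). The ceh homeobox genes had 5 of 63 (exact adjusted p = 1), ceh-60 and ceh-37 (382), ceh-99 (313, shared with srh-70), ceh-38 (196, shared with malt-1) and ceh-19 (168, shared with csr-1 and frpr-10). The hlh genes had 2 of 25 (exact adjusted p = 1), hlh-13 (294) and hlh-11 (99.7). MicroRNA genes had 30 of 261 (exact adjusted p = 0.136), including cel-mir-77 (313, the summit of ceh-99) and the cluster cel-mir-54, cel-mir-55 and cel-mir-56 (210, 1 shared summit). With a 2 kb upstream window the microRNA list passed the threshold (log2 odds ratio 0.85, exact adjusted p = 0.00294), the 1 alternative of 9 in which it did. Lists of 12 to 26 genes leave wide intervals, so a share that missed the threshold is not shown to equal the background.

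**Figure D3:**
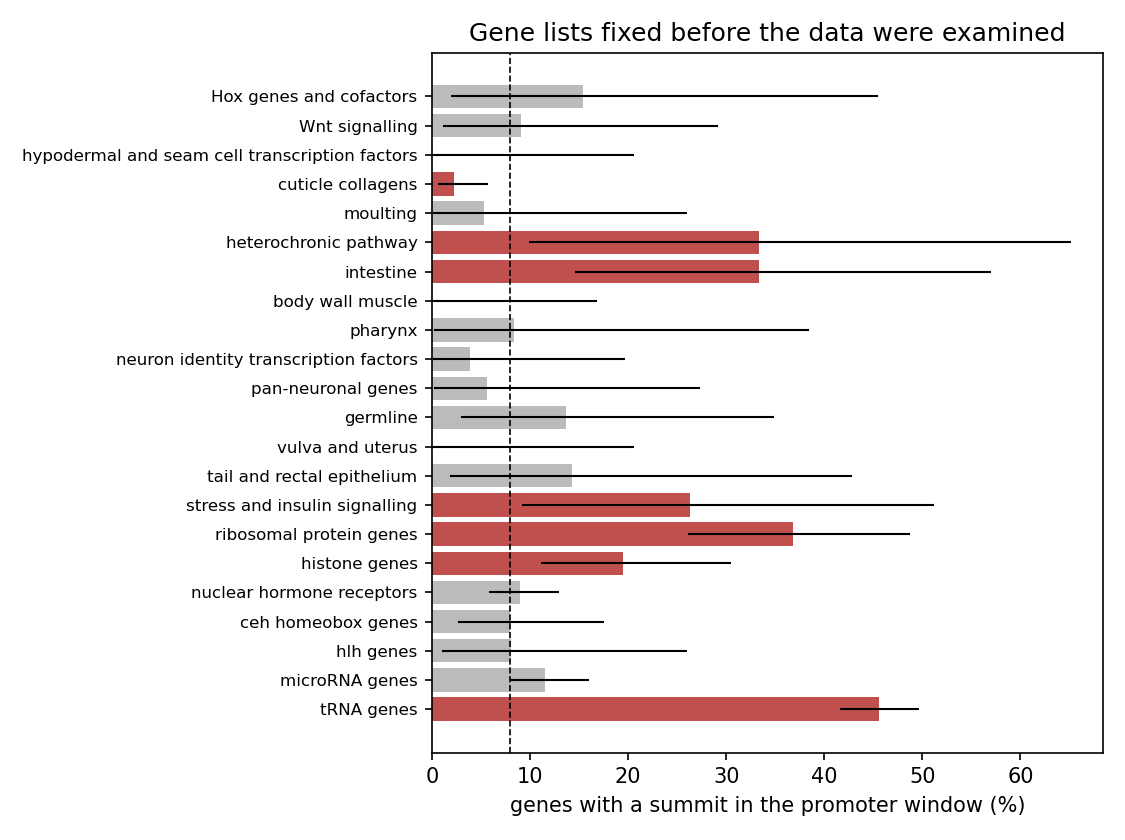
Share of genes with a summit in the promoter window (x axis, %) for each of 22 gene lists; lines are exact binomial 95% intervals, red bars passed the adjusted threshold of 0.05 and the dashed line marks the share among other protein-coding genes. tRNA genes reach 45.6%, ribosomal protein genes 36.8% and cuticle collagens 2.27%.

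Posterior Hox sequences were more frequent at summits than beside them, and in that comparison the GATA, GAGAGA and E-box motifs had higher ratios in the main list. The strict posterior Hox motif TTTATGR was in 8.43% of summit windows (50 bp to each side) and 5.08% of windows 400 bp to either side (log2 ratio 0.73 ± 0.11 (SE), exact adjusted p = 1.05e-10), and the wider TTTAYKR in 24.7% against 19.4% (0.34 ± 0.05, exact adjusted p = 1.20e-09). The PBC-Hox composite TGATTDAT was in 3.54% against 2.39% (0.57 ± 0.17, exact adjusted p = 0.000983). The GATA motif WGATAR was in 41.1% of summit windows against 20.9% (0.98 ± 0.04, exact adjusted p = 7.39e-103), GAGAGA in 13.0% against 5.52% (1.23 ± 0.09, exact adjusted p = 1.59e-37) and the E-box CACGTG in 5.39% against 1.63% (1.73 ± 0.17, exact adjusted p = 2.10e-25). The nuclear receptor motif AGGTCA was in 3.60% against 2.45% (0.56 ± 0.17, exact adjusted p = 0.000994). The general Hox core TAATKR (17.8% against 21.2%, exact adjusted p = 3.96e-05) and TATAAA (9.05% against 11.98%, exact adjusted p = 5.93e-06) were less frequent at summits. So was the scrambled control TAYRTKT, which holds the letters of the posterior Hox motif in another order (14.3% against 18.05%, log2 ratio −0.33 ± 0.07, exact adjusted p = 1.87e-06). Against shuffles of the summit windows that keep dinucleotides, TATAAA (log2 ratio 0.32) and the scrambled control (0.23) turned to an excess, and AGGTCA no longer passed the threshold (0.07), while both posterior Hox motifs, the composite, GATA, GAGAGA and the E-box passed it in the same direction. There the log2 ratio of the strict posterior Hox motif was 1.12, near that of GATA (1.15), above that of GAGAGA (0.92) and below that of the E-box (1.38). Without replicate 1 the log2 ratio to flanking windows was 1.104 for the strict motif, 0.56 for the wider one and 0.96 for the composite, which was 0.94 without replicate 2. In the list without replicate 1, GATA (1.13), GAGAGA (1.08) and the strict motif were close, and the E-box had 1.72. The lower share of TAATKR was not called in the stronger-signal part of the list or without replicate 1 (log2 ratio −0.11) or replicate 2 (−0.14), nor that of TATAAA without replicate 2 (−0.16). The scrambled control's log2 ratio was −0.21 without replicate 2. The test did not pair each summit with the windows beside it, and neighbouring peaks are not independent. The p-values and SEs of these motif shares are therefore approximate.

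**Figure D4:**
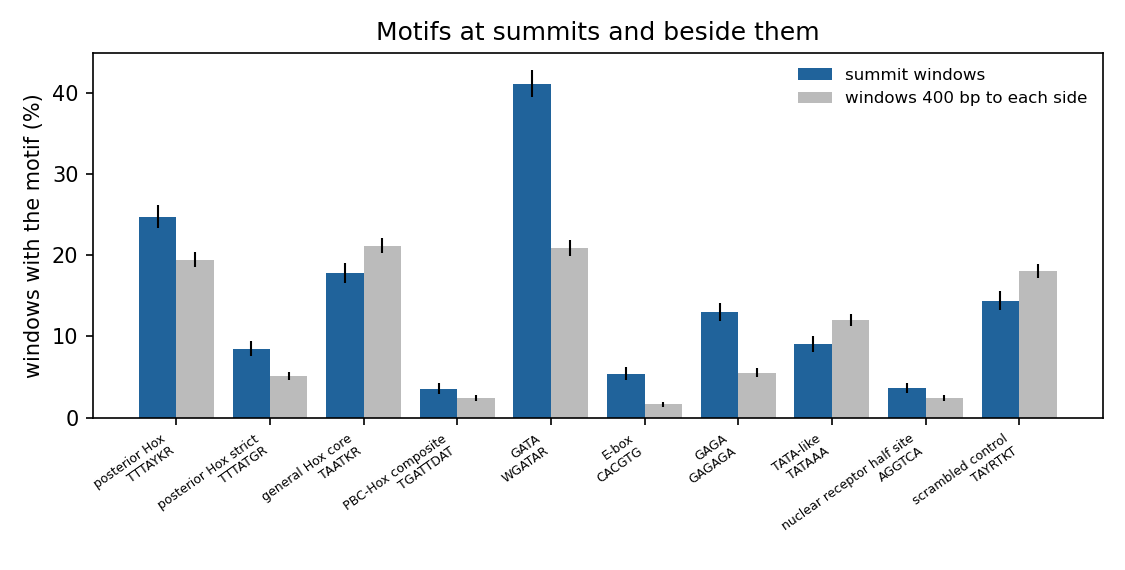
Share of windows holding each of 10 motifs (y axis, %) at 3559 summits and in windows 400 bp to each side; lines are exact binomial 95% intervals. The GATA motif has the highest share at summits, 41.1% against 20.9%, and the strict posterior Hox motif 8.43% against 5.08%.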

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

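All tests in this part were chosen after the pattern they address was seen. For the test of tRNA copies alone, the prediction was written before the outcome of that test was known. Some peaks in data outside the report's comparisons were above the threshold yet missing from the thresholded lists. At or above the lowest score kept, the thresholded lists left out 75 peaks of the series-wide list that pairs the replicates, 76 of the other series-wide list, 60 of replicate 1's and 50 of replicate 2's. The strongest was the highest of all ranked peaks, on X (15810932 to 15811184), with a signal value of 3411 against 1143 for the highest kept, and 1989 and 1658 in the replicates; a pseudogene, WBGene00044155, lies within 1 kb. The listing names a further input for the thresholded lists, whose nature is not given in the sources used here, and no explanation was tested.

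The excess of summits on X was weighed against 3 technical explanations. Without summits within 1 kb of a tRNA gene, 719 of 3308 summits (21.7%) were on X, and the ratio to its gene share was 1.59 (95% interval from 1.49), which argues against tRNA genes as the whole cause. With the same summits left out, the ratio to its share of chromosome length was 1.23 (interval from 1.15), so the length of X does not account for all of it. With tRNA summits also left out, 16.38% of ranked peaks under the threshold were on X. The odds were 1.42 times higher (interval from 1.303) among the 3308 thresholded summits. The ranked peaks came from the list that pairs the replicates, which held 3539 of the larger list's 3559 summits. Only 2974 of those 3559 were in the conservative list kept from it. Some thresholded summits were therefore also counted under the threshold, although the interval treats the groups as separate. The comparison cannot decide on a gain of coverage on X, since such a gain would itself lift more X peaks over the threshold. Neighbouring peaks are not independent, so these intervals are too narrow, and no biological explanation was tested.

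The peaks at tRNA genes were also weighed. Of 143 tRNA genes whose sequence occurs once among tRNA genes, 31 (21.7%, exact 95% interval 15.2 to 29.3) had a summit within 100 bp. That was above the 7.95% of protein-coding promoters, whose window has another length. Only identical sequences counted as copies. Nearly identical genes may still share reads, and a close neighbour with copies may lend its summit, so shared reads are not excluded. The share was higher in the 469 genes with copies (42.2%, Fisher's exact p = 7.62e-06), so reads shared between copies may add to it. At 251 tRNA summits the strict posterior Hox motif had a log2 ratio to flanking windows of 0.20, against 0.77 at other summits, with an upper 95% limit of 1.09. The wider motif had a log2 ratio of −0.40 there (upper limit 0.09), under the 0.39 of other summits, and the PBC-Hox composite was in 0 of 251 windows against 2.80% of flanking windows (exact adjusted p = 0.0186). Flanking windows may differ from tRNA summits in base composition, as the scrambled control was also lower there (−0.69). Against dinucleotide shuffles the wider motif's log2 ratio was 0.50 (exact adjusted p = 0.117), with an upper limit of 0.95 against 0.86 at other summits, the scrambled control's was 0.66, and the composite did not differ (exact adjusted p = 0.444). The strict motif's log2 ratio to shuffles was 0.77 ± 0.39 (SE, exact adjusted p = 0.117), above the scrambled control's but with wide limits. For the wider motif no excess over the scrambled control was shown against shuffles. As the limits are wide, binding through either motif stays open. Recovery of highly transcribed genes whatever the tagged protein stays open. Ribosomal protein and histone genes were also raised in the main list, and collagen genes were not (upper 95% limit of the log2 odds −0.38). The ribosomal protein call passed the threshold in 10 of 10 alternatives, and the histone and collagen calls in 7 of 10 each. Without replicate 2 the histone log2 odds ratio was −0.31. Of 20 rRNA genes, 0 had a summit in the window, but whether peaks could be called at them is unknown, so that count decides nothing. Transcription and an untagged control were not analysed here. No biological explanation was tested.

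The list held 174 peaks of signal under 50, some as low as 2.09. Of these, 98.3% lay within 400 bp of a stronger listed peak (median 203 bp), against 0.502% of the other 3385. That pattern would be seen for second summits carried into the list by the paired input peaks of a stronger neighbour. The limit of 50 and the distance were both set after these values were seen.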

How the results depend on the processing

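For the results that answer a comparison, 60 alternative values kept their direction and side of the threshold or, for counts, stayed within 1.5 times, and 13 moved. The promoter ratio (1.47 to 2.34), the X ratio (1.33 to 1.85), the difference in promoter signal (4.65 to 11.3) and the log2 odds of central segments (0.12 to 0.37) passed the threshold in every alternative run. Replicate overlap was 65.7% with 50% of both intervals and 70.0% with summits within 100 bp. Spearman's rho was 0.42 over the ranked peaks that could be matched in both replicates and 0.25 by q value. Of the gene lists, 6 were higher and 1 lower in the main result. In the stronger-signal part of the list 2 were higher and 0 lower, with fewer peaks; by nearest 5′ end, 3 and 0, of the 20 lists of coding genes. With a 500 bp window 0 were lower, and the cause was not tested. Without either replicate, 2 to 4 lists were higher, and the histone log2 odds ratio was −0.31 to 1.78; the cause was not tested. Leaving out summits near tRNA genes, chosen after seeing the data, gave 2 lower lists, as it removes the tRNA summits (log2 odds ratio −6.67). Motifs lower at summits numbered 3 in the main result, 1 to 2 without either replicate, and 1 against shuffles, where TATAAA (0.32) and the scrambled control (0.23) were reversed; the cause was not tested. On chromosome III the ratio fell from 1.11 to 0.9994 in the stronger-signal part of the list; the cause was not tested. For single lists, motifs, locations and chromosomes other than X, 335 values stayed the same, 33 lost the threshold, 10 gained it and 5 changed direction. No paired analysis was possible because there is 1 group. Depth is unknown, so its limits could not be set.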

Other observations

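All tests in this part were chosen after the data were seen. Small non-coding RNA genes other than tRNA genes also stood near summits. Of 346 snoRNA genes, 103 (29.8%) had a summit in the window used for promoters, as did 33 of 129 snRNA genes (25.6%), against 7.95% of protein-coding genes. The share was 10.3% of 194 lincRNA genes, 2.82% of 2128 pseudogenes and 1.57% of 15363 piRNA genes. Many snoRNA genes lie inside other genes, so their windows overlap those of their hosts, and these shares were not tested. On X, 116 of 276 tRNA genes (42.03%) had a summit within 100 bp, against 29.5% on V to 42.1% on II among the autosomes.

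Motif shares were also compared by peak strength and by location. Without tRNA summits and peaks of signal under 50, the strict posterior Hox motif was in 13.98% of 787 summit windows in the quartile of highest signal and in 5.21% of the lowest (Fisher's exact test, adjusted p = 1.12e-08). From the lowest to the highest quartile the PBC-Hox composite went from 1.78% to 6.23%, the GATA motif from 30.1% to 52.0%, the E-box from 3.43% to 8.01% (exact adjusted p = 0.000242) and TAATKR from 16.3% to 22.1% (exact adjusted p = 0.00560). Over the 4 quartiles from the lowest, the strict motif was in 5.21%, 7.24%, 9.28% and 13.98% and the wider one in 18.4%, 21.1%, 26.2% and 37.6%. The scrambled control was in 10.8%, 15.1%, 15.9% and 15.9% (lowest against highest, exact adjusted p = 0.00560), so a rise from the lowest quartile was not limited to the motifs of known factors; no test compared the motifs, and the cause was not tested. GAGAGA (9.91% to 12.8%, exact adjusted p = 0.101), TATAAA (8.51% to 10.7%, exact adjusted p = 0.190) and AGGTCA (3.68% in both) did not pass the threshold. Between promoter and other summits the GATA share was 43.4% against 42.3% (exact adjusted p = 0.777) and the strict posterior Hox share 9.01% against 8.34% (exact adjusted p = 0.777); TATAAA was more frequent at promoter summits (11.0% against 7.93%, exact adjusted p = 0.0325).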
